A study of Mus musculus with 12 samples.

How the data were processed

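The series measured gene expression in mouse embryonic fibroblasts (MEFs) on Affymetrix Mouse Genome 430A 2.0 arrays. Per the labels, the fibroblasts were prepared from embryos and moved to a serum-containing medium with basic fibroblast growth factor. They were then treated with 1 of 2 chemical combinations known here by the code names 6TCF and SGCF. Each combination has its own arrays at days 0, 5 and 10, with 2 arrays per group, 6 groups and 12 arrays in all. None of the 12 arrays is labelled as an untreated or vehicle culture at day 5 or 10. Changes from day 0 therefore also hold time in culture and any change of medium. In both arms, the labels give 10% fetal bovine serum for the fibroblast medium and 15% for the medium with the chemicals. The components of the combinations are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and every array could be placed in a group. The labels do not say whether the replicates of a group are separate embryos or separate cultures, so p-values may measure technical spread between these arrays.

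The deposited values are linear intensity values per probe set, with 22690 probe sets on each array. The submitters' processing notes name RMA, limma and MAS5 without versions or roles, so which of them made the deposited intensity values is not given in the sources used here. The lowest value on an array was 3.97 to 6.04 and the highest 16601.3 to 27193. Array medians were 102.4 to 142 in the 6TCF arm and 60.9 to 86.2 in the SGCF arm, so the values had not been brought to a common scale between arrays. On each array, 99.68% to 99.75% of the values of 60 or more shared 1 decimal part within 0.002. No origin for this pattern is given in the sources used here.

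The design written before the data were examined allowed for values already normalized between arrays. Because the values were not, quantile normalization between arrays was applied, and everything reported is on the log2(intensity + 16) scale, which understates the change of dim genes. Array brightness coincided with the arm. For comparisons between the arms, a processing batch and the arm therefore cannot be told apart. The 64 control probe sets were used only for RNA quality, as the log2 difference between the 3' and 5' probe sets of actin and of Gapdh.

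Of the 22690 probe sets, 20380 had exactly 1 gene symbol in the platform annotation, 691 had several and 1555 were unnamed here. Probe sets with several symbols named no gene. Of the 20380, 20351 symbols were found by Entrez gene number in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Each of 12393 genes was represented by its probe set with the highest mean. Genes were kept when their highest group mean lay above the 25th percentile of all values, log2 5.25, which left 10674 genes.

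Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) on all 12 arrays with 6 group means, with 6 residual and 5.75 prior degrees of freedom. Benjamini-Hochberg adjustment ran over the 10674 genes, and a gene was called at an adjusted p under 0.05. The subset changed at least 2-fold was counted as well. There were 9 comparisons: days 5 and 10 against day 0 and day 10 against day 5 within each arm, SGCF against 6TCF at day 0, and the difference between the arms in the change from day 0 by day 5 and by day 10. The arms were also set against each other directly at days 5 and 10. Errors are standard errors (SE) of the log2 change from this fit or standard deviations (SD) over the arrays of a group. The number of arrays limits the precision.

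Before the data were examined, 23 gene lists with 490 entries were fixed. They were fibroblast identity, TGF-beta and myofibroblast genes, Wnt/beta-catenin targets, cAMP/CREB targets, epithelial genes, neuronal genes, neural stem, glial and neural crest genes, cardiac genes, skeletal muscle genes, adipocyte genes, endoderm and liver genes, pluripotency genes, cell cycle genes, growth arrest and secretory senescence genes, interferon-stimulated genes, cholesterol synthesis genes, glycolysis and hypoxia genes, and integrated stress and unfolded protein response genes. Markers of other cells that fibroblast cultures can hold formed the rest: macrophage markers, endothelial markers, cartilage and bone markers, keratinocyte markers, and Y-linked genes with Xist. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 22 lists with at least 5 measured genes within each comparison. Camera with a correlation estimated per list and the rotation test fry were alternatives. Member counts are given over all genes tested and adjusted over the list alone.

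The genes named in the text follow a rule fixed at the same time. Against day 0 and for the differences, the rule takes the 8 largest rises and 8 largest falls among called genes changed at least 2-fold. In comparisons of 2 groups, it also asks for no overlap between their arrays, a condition not applied to the differences. It takes 5 and 5 for day 10 against day 5 and for the day 0 comparison. It adds up to 4 called members of each list with the largest change, or the 1 member with the largest change where none was called. Predicted transcripts were skipped. Of 775 called pairs of named gene and comparison, 296 had another measured probe set for the same gene, and in 3 of them another probe set was called in the opposite direction: Rsad2 under 6TCF by day 5, Ndrg1 under SGCF by day 5 and Mbp at day 0.

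The fit was tested on simulated data built from means and spreads of the genes in the real data. In each of 20 draws, 200 of 10674 genes were changed. For 6TCF at day 5 against day 0, it recovered 24% of genes changed by 0.5 on the log2 scale, 93.3% of those changed by 1 and 97.4% of those changed by 2, and 4.89% of calls were false. For the difference by day 5, the shares were 5.37%, 64.3% and 94.6%, and 5.29% of calls were false. The real data gave 2958 and 958 calls in these comparisons, so the simulation held fewer changed genes than were called. Its shares may not carry over to the real data. Camera called the raised list in 20 of 20 draws and 1 of 420 unchanged lists. These lists were random genes with independent noise, so the simulation does not test the preset correlation.

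Alternatives fixed before the data were examined were median scaling, no filter or a filter at the 50th percentile, the mean of a gene's probe sets or every probe set on its own, a trended robust eBayes, fits of the compared groups alone, a replicate block, all 4 day 0 arrays as 1 group, direct comparison of the arms, and leaving out each array. No scaling, cyclic loess and no pseudocount were added after the data were seen. Figures were drawn with matplotlib 3.10.9.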

Results

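Gene expression was measured in mouse embryonic fibroblasts under the chemical combinations 6TCF and SGCF, whose components are not given in the sources used here. Each combination had 2 arrays at day 0, 2 at day 5 and 2 at day 10, and 10674 genes were tested on the 12 arrays. Array medians of the deposited intensity were 102.4 to 142 in the 6TCF arm and 60.9 to 86.2 in the SGCF arm, and the number of arrays limits the precision. After normalization, the 2 arrays of a group correlated across genes at r = 0.985 to 0.997 and arrays of different groups at 0.925 to 0.983, where genes are not independent replicates. The first principal component held 46.3% of the variance and the next 19.7%. The 3' minus 5' signal of the actin control probe sets, which grows as transcripts lose their 5' ends, was 0.34 ± 0.06 at day 0, 0.82 ± 0.08 at day 5 and 1.04 ± 0.004 at day 10 of 6TCF on the log2 scale (SD, n = 2). In the SGCF arm it was 0.33 ± 0.08, 0.45 ± 0.04 and 0.46 ± 0.01 (SD, n = 2). For the Gapdh control the means were 0.39, 0.50 and 0.49 in the 6TCF arm and -0.02, 0.10 and 0.11 in the SGCF arm (n = 2 each). All changes below are log2 changes with their SE, with 2 arrays in each group.

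By day 5 of 6TCF, some genes of the extracellular matrix rose and others fell. Lum, which encodes the small matrix proteoglycan lumican, rose by 5.20 ± 0.15, from 7.31 ± 0.24 to 12.51 ± 0.02 (SD, n = 2), and the collagen-binding proteoglycan gene Dcn rose by 2.89 ± 0.13. Ccn2, a connective tissue growth factor induced by TGF-beta, changed by -3.65 ± 0.13, Lox, whose enzyme crosslinks collagen, by -2.95 ± 0.18 and Col8a1, a collagen chain, by -3.22 ± 0.16. The growth factor gene Bmp2 rose by 5.00 ± 0.26, the carbonic anhydrase gene Car3 by 4.76 ± 0.17 and Gria1, a glutamate receptor subunit, by 4.43 ± 0.15. The comparison addresses what the series' title is about, the conversion of fibroblasts toward several lineages, at its earlier time.

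Among TGF-beta and myofibroblast genes under 6TCF at day 5, 18 of 21 fell, 2 rose and 1 was not called, with the same counts adjusted over the list alone. Their median was -0.99 (camera adjusted p = 5.8e-10, adjusted p = 0.101 with an estimated correlation). Igfbp3, which binds insulin-like growth factors, was 1 of the 2 that rose (2.59 ± 0.14). Wnt/beta-catenin targets rose, 11 of 17 against 2 that fell and 4 not called (12 and 2 adjusted over the list alone). Their median was 1.5 (adjusted p = 1.01e-06, adjusted p = 0.0826 with an estimated correlation). They included the receptor gene Tnfrsf19 (4.22 ± 0.18), Notum, which inactivates secreted Wnt (3.17 ± 0.14), and the feedback inhibitor Axin2 (3.07 ± 0.13). Growth arrest and secretory senescence genes rose as well, with 11 of 16 up, 1 down and 4 not called, the same 11 and 1 adjusted over the list alone. Their median was 1.01 (adjusted p = 1.01e-06, adjusted p = 0.0539 with an estimated correlation). Among them were the matrix protease gene Mmp3 (4.06 ± 0.16) and the cyclin-dependent kinase inhibitor gene Cdkn1c (2.02 ± 0.11). Fibroblast identity genes were divided, with 14 of 25 up, 7 down and 4 not called (15 and 7 adjusted over the list alone). Their median was 0.52 (adjusted p = 0.00682, adjusted p = 0.394 with an estimated correlation). Lum and Dcn were among those that rose, and Fbln2, an elastic fibre protein gene, fell by 2.75 ± 0.22.

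Genes of other lineages also changed under 6TCF by day 5. Epithelial genes rose in 9 of 19 cases, fell in 2 and were not called in 8 (10 and 2 adjusted over the list alone). Their median was 0.51 (adjusted p = 0.0108, adjusted p = 0.101 with an estimated correlation). The keratin gene Krt18 rose by 2.13 ± 0.18 and Krt8 by 1.61 ± 0.26. Of 18 neural stem, glial and neural crest genes, 8 rose, 1 fell and 9 were not called (8 and 2 adjusted over the list alone). Their median was 0.21 (adjusted p = 0.0182, adjusted p = 0.101 with an estimated correlation), and the neural progenitor transcription factor gene Sox2 rose by 2.85 ± 0.22. Neuronal genes as a list were not called (6 of 18 rose, 2 fell, median 0.16, adjusted p = 0.0645), although the neurofilament gene Nefl rose by 3.88 ± 0.39 and the growth cone gene Gap43 by 2.89 ± 0.15. Cartilage and bone markers fell, 5 of 11 against 1 that rose and 5 not called, with the same counts adjusted over the list alone. Their median was -0.25 (adjusted p = 0.0238, adjusted p = 0.101 with an estimated correlation), and the list held the cartilage collagen genes Col11a1 (-2.70 ± 0.23) and Col2a1 (-2.33 ± 0.14).

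Macrophage markers fell in the same arrays, 14 of 18 against 1 that rose and 3 not called, with the same counts adjusted over the list alone. Their median was -1.24 (adjusted p = 5.98e-09, adjusted p = 0.0826 with an estimated correlation). The lysosomal protease gene Ctss changed by -3.21 ± 0.29 and the complement gene C1qa by -2.45 ± 0.14. Cholesterol synthesis genes fell in 11 of 17 cases, rose in 1 and were not called in 5 (12 and 1 adjusted over the list alone). Their median was -0.61 (adjusted p = 5.82e-05, adjusted p = 0.149 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps changed by -1.14 ± 0.13. Integrated stress and unfolded protein response genes fell in 10 of 22 cases, rose in 2 and were not called in 10 (11 and 2 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.0133, adjusted p = 0.101 with an estimated correlation). The asparagine synthetase gene Asns changed by -1.38 ± 0.15. The actin 3' minus 5' signal stood 0.48 higher than at day 0 in these arrays, and that of Gapdh went from 0.39 to 0.50.

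The remaining lists were not called at day 5 of 6TCF. Glycolysis and hypoxia genes had 5 of 21 up and 9 down (adjusted p = 0.145), endoderm and liver genes 4 of 14 up and 0 down (0.0665), interferon-stimulated genes 3 of 16 up and 1 down (0.508), adipocyte genes 3 of 14 up and 1 down (0.432) and cAMP/CREB targets 5 of 18 up and 3 down (0.595). Cell cycle genes had 0 of 28 up and 2 down (0.351), endothelial markers 5 of 15 up and 3 down (0.792), skeletal muscle genes 1 of 16 up and 1 down (0.794), pluripotency genes 2 of 12 up and 1 down (0.842), cardiac genes 2 of 21 up and 4 down (0.955) and keratinocyte markers 2 of 11 up and 2 down (0.955). Of the 4 measured Y-linked genes and Xist, too few to test as a list, 1 was called. In all, limma called 2958 genes, 1617 higher and 1341 lower, of which 563 and 275 changed at least 2-fold. Without 6TCF day 0 replicate 1 the count was 1852, and without 6TCF day 0 replicate 2 it was 1757.

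**Figure D1:**
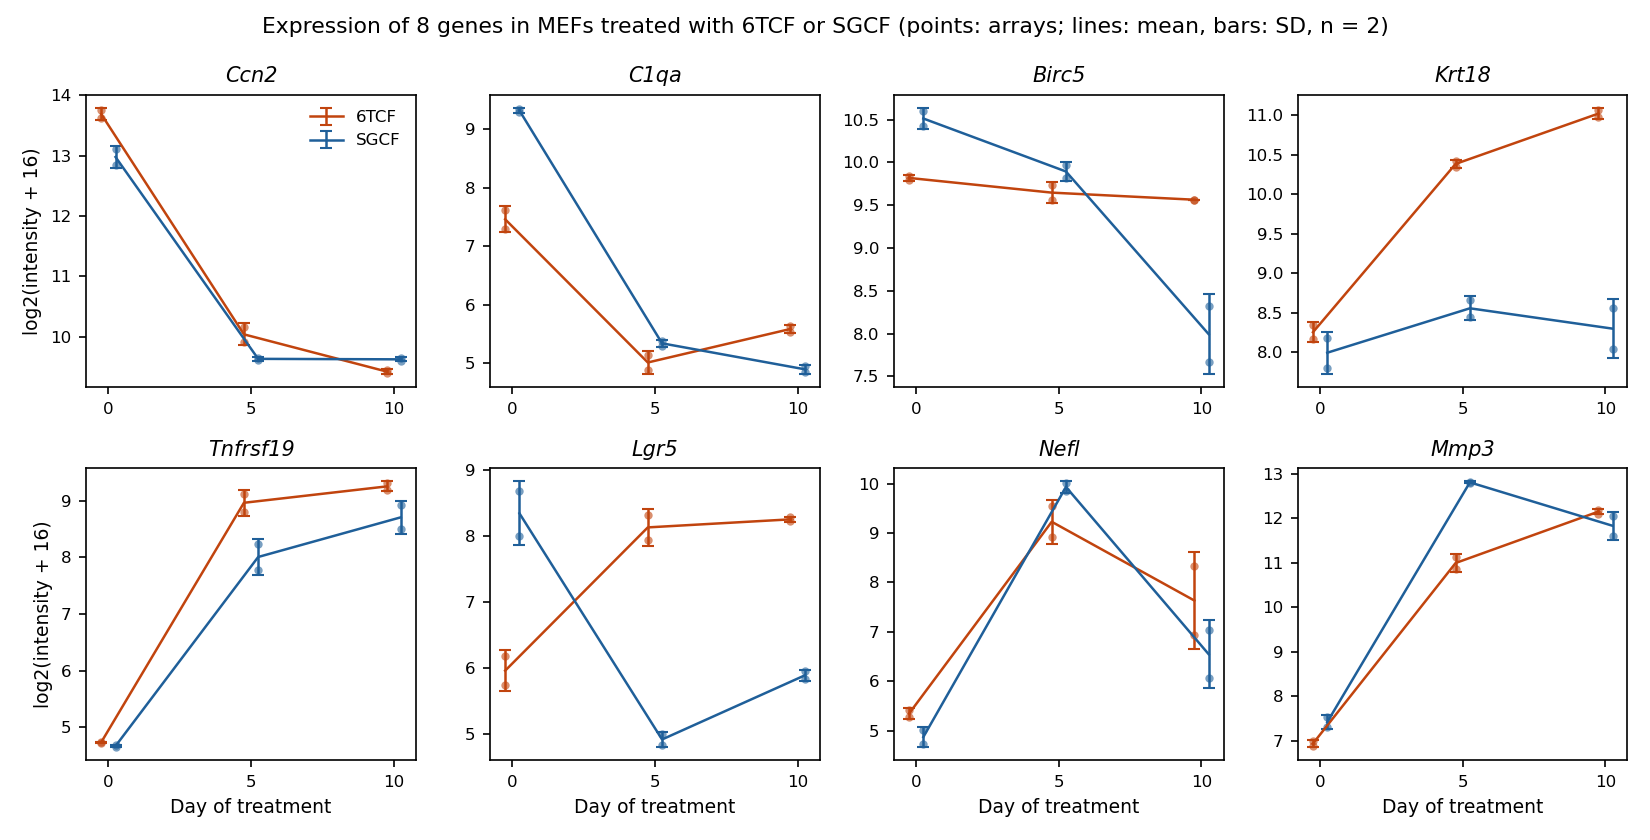
Normalized log2(intensity + 16) of 8 genes against the day of treatment, where points are arrays and lines join the group means with SD bars (n = 2), orange for 6TCF and blue for SGCF. Ccn2 started at 13.69 and 12.98 and lay at 9.42 and 9.62 at day 10, while Lgr5 went from 5.96 to 8.25 under 6TCF and from 8.34 to 5.89 under SGCF.

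By day 10 of 6TCF, the acute-phase gene Saa3 had risen by 6.73 ± 0.25, from 5.94 ± 0.36 to 12.66 ± 0.10 (SD, n = 2), and the chemokine gene Ccl8 by 6.57 ± 0.22. Mmp3 rose by 5.21 ± 0.16 and Lum by 5.23 ± 0.15, while Ccn2 changed by -4.27 ± 0.13, Col11a1 by -4.24 ± 0.23 and Col8a1 by -4.17 ± 0.16. Hbegf, a growth factor that binds the EGF receptor, changed by -3.64 ± 0.24. This comparison gives the state reached at the last time measured.

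Of the TGF-beta and myofibroblast genes, 18 of 21 were lower at day 10 of 6TCF, 2 were higher and 1 was not called, with the same counts adjusted over the list alone. Their median was -1.86 (adjusted p = 1.68e-10, adjusted p = 0.143 with an estimated correlation). Wnt/beta-catenin targets were higher in 10 of 17 cases, lower in 2 and not called in 5 (11 and 2 adjusted over the list alone). Their median was 1.49 (adjusted p = 0.000343, adjusted p = 0.143 with an estimated correlation). Tnfrsf19 changed by 4.51 ± 0.18. Growth arrest and secretory senescence genes were higher in 10 of 16 cases, lower in 1 and not called in 5, with the same counts adjusted over the list alone. Their median was 1.18 (adjusted p = 3.74e-05, adjusted p = 0.0987 with an estimated correlation), and the neutrophil chemokine gene Cxcl1 was among them at 2.77 ± 0.20. Cell cycle genes fell in 14 of 28 cases and rose in 0, with 14 not called and the same counts adjusted over the list alone. Their median was -0.40 (adjusted p = 0.00112, adjusted p = 0.47 with an estimated correlation). The proliferation marker Mki67 fell by 1.30 ± 0.24 and the ribonucleotide reductase gene Rrm2 by 0.75 ± 0.15.

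Interferon-stimulated genes rose in 9 of 16 cases by day 10 of 6TCF and fell in 0, with 7 not called and the same counts adjusted over the list alone, among them the guanylate-binding protein genes Gbp2 (3.73 ± 0.25) and Gbp3 (2.37 ± 0.37). The list's median was 0.50 (adjusted p = 0.00211, adjusted p = 0.161 with an estimated correlation), and with all 4 day 0 arrays as 1 group the adjusted p was 0.129. Macrophage markers fell in 12 of 18 cases, rose in 2 and were not called in 4, the same adjusted over the list alone. Their median was -0.87 (adjusted p = 3e-04, adjusted p = 0.161 with an estimated correlation), and C1qa changed by -1.88 ± 0.14. Cholesterol synthesis genes fell in 12 of 17 cases, rose in 1 and were not called in 4, the same adjusted over the list alone. Their median was -0.53 (adjusted p = 0.000676, adjusted p = 0.211 with an estimated correlation). Fdps changed by -1.37 ± 0.13 and the lanosterol synthase gene Lss by -0.95 ± 0.12. Cartilage and bone markers fell in 5 of 11 cases and rose in 0, with 6 not called and the same counts adjusted over the list alone. Their median was -0.50 (adjusted p = 0.012, adjusted p = 0.143 with an estimated correlation).

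Epithelial genes were higher in 10 of 19 cases at day 10 of 6TCF, lower in 2 and not called in 7, the same adjusted over the list alone. Their median was 0.52 (adjusted p = 0.00779, adjusted p = 0.143 with an estimated correlation). Krt18 rose by 2.77 ± 0.18, Krt8 by 2.31 ± 0.26 and the cell adhesion gene Epcam by 1.89 ± 0.21. In the same arrays 11 of 14 mesothelium genes, from a list written after day 0 values had been seen, were also higher and 1 was lower (median 1.23). The albumin gene Alb rose by 2.66 ± 0.23 and the hepatic transcription factor gene Foxa2 by 1.58 ± 0.12, while endoderm and liver genes as a list were not called (5 of 14 up, 1 down, adjusted p = 0.0853). Skeletal muscle genes were not called as a list either (8 of 16 up, 2 down, median 0.67, adjusted p = 0.0976). The fast muscle troponin gene Tnnc2 rose by 2.84 ± 0.59, and the light chain gene Mylpf (2.37 ± 0.65) and the embryonic myosin gene Myh3 (1.97 ± 0.48) were called, but without 6TCF day 10 replicate 2 Tnnc2 stood at 1.70, Mylpf at 1.09 and Myh3 at 1.05, and the last 2 were not called. Mylpf also lost its call without 6TCF day 0 replicate 2 (2.35) and stood at 3.65 without 6TCF day 10 replicate 1. Of the 10674 genes, 4616 were called, 2478 higher and 2138 lower, of which 807 and 495 changed at least 2-fold, and the actin 3' minus 5' signal stood 0.69 above that of day 0 and the Gapdh signal 0.10 above.

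Between days 5 and 10 of 6TCF, Saa3 rose further by 2.96 ± 0.25, Retnla, a gene induced by type 2 cytokines, by 2.75 ± 0.23, the corneal proteoglycan gene Kera by 2.46 ± 0.15 and Ccl8 by 2.45 ± 0.22. Hmga2, a chromatin protein gene of proliferating embryonic cells, changed by -1.69 ± 0.20 and Map1b, which encodes a microtubule protein of growing axons, by -1.66 ± 0.22. Sox2 fell by 1.53 ± 0.22 after its rise to day 5, and Epcam rose by 1.36 ± 0.21. The comparison separates later from earlier changes.

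TGF-beta and myofibroblast genes fell further in 14 of 21 cases from day 5 to day 10 of 6TCF and rose in 0 (15 and 0 adjusted over the list alone). Their median was -0.53 (adjusted p = 7.73e-07, adjusted p = 0.304 with an estimated correlation). Col8a1 changed by -0.94 ± 0.16. Interferon-stimulated genes rose in 6 of 16 cases and fell in 0 (9 and 0 adjusted over the list alone). Their median was 0.54 (adjusted p = 1.36e-05, adjusted p = 0.264 with an estimated correlation). Gbp2 changed by 2.39 ± 0.25 and the immunoproteasome gene Psmb8 by 1.04 ± 0.13. In the same step macrophage markers rose in 9 of 18 cases and fell in 0, the same adjusted over the list alone. Their median was 0.51 (adjusted p = 0.000171, adjusted p = 0.304 with an estimated correlation), and the macrophage surface gene Adgre1 rose by 0.75 ± 0.12. Cell cycle genes fell in 6 of 28 cases and rose in 0 (12 and 0 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.000198, adjusted p = 0.649 with an estimated correlation, adjusted p = 0.101 with fry). Neuronal genes fell in 6 of 18 cases and rose in 0 (7 and 0 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.00318, adjusted p = 0.304 with an estimated correlation). The synaptic vesicle gene Syn1 changed by -1.35 ± 0.13 and the neurofilament gene Nefm by -1.15 ± 0.17, and the list's adjusted p was 0.077 without 6TCF day 10 replicate 1. Skeletal muscle genes rose in 4 of 16 cases and fell in 0 (8 and 0 adjusted over the list alone). Their median was 0.53 (adjusted p = 0.0459, adjusted p = 0.649 with an estimated correlation). That adjusted p was 0.147 without 6TCF day 5 replicate 1, 0.0572 without day 5 replicate 2 and 0.453 without day 10 replicate 2. The genes called numbered 1688, with 928 higher and 760 lower, of which 154 and 77 changed at least 2-fold. The count fell to 373 without 6TCF day 5 replicate 1, 370 without day 10 replicate 1 and 694 without day 10 replicate 2.

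By day 5 of SGCF, Bmp2 rose by 6.55 ± 0.26, Mmp3 by 5.39 ± 0.16, the neuronal pentraxin gene Nptx1 by 5.16 ± 0.32 and Nefl by 5.07 ± 0.39. Aspn, which encodes a small matrix proteoglycan, changed by -5.49 ± 0.38, Lox by -4.11 ± 0.18, the matrix protein gene Postn by -3.75 ± 0.13 and the lysozyme gene Lyz2 by -4.06 ± 0.26. Sox2 rose by 2.58 ± 0.22. The comparison asks of SGCF what was asked of 6TCF at the same time.

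Macrophage markers fell in 16 of 18 cases by day 5 of SGCF, rose in 1 and were not called in 1, the same adjusted over the list alone. Their median was -2.61 (adjusted p = 9.44e-19). That call held with an estimated correlation (adjusted p = 0.0175), and C1qa fell by 3.98 ± 0.14. TGF-beta and myofibroblast genes fell in 16 of 21 cases, rose in 2 and were not called in 3 (16 and 3 adjusted over the list alone). Their median was -2.06 (adjusted p = 8.85e-14, adjusted p = 0.0794 with an estimated correlation). Ccn2 changed by -3.35 ± 0.13. Integrated stress and unfolded protein response genes fell in 15 of 22 cases, rose in 2 and were not called in 5, the same adjusted over the list alone. Their median was -0.86 (adjusted p = 4.15e-08, adjusted p = 0.0175 with an estimated correlation). Asns changed by -1.67 ± 0.15. The cystine transporter gene Slc7a11 of that list rose by 2.16 ± 0.17. Cholesterol synthesis genes fell in 13 of 17 cases and rose in 0, with 4 not called (14 and 0 adjusted over the list alone). Their median was -0.85 (adjusted p = 8.19e-10, adjusted p = 0.0794 with an estimated correlation). Fdps and the sterol demethylase gene Cyp51 both changed by -1.84 (SE 0.13 and 0.14). Cell cycle genes fell in 20 of 28 cases and rose in 0, with 8 not called (23 and 0 adjusted over the list alone). Their median was -0.58 (adjusted p = 4.47e-08, adjusted p = 0.235 with an estimated correlation), and the spindle motor gene Kif20a fell by 0.94 ± 0.16.

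Wnt/beta-catenin targets rose in 10 of 17 cases by day 5 of SGCF, fell in 3 and were not called in 4 (11 and 3 adjusted over the list alone). Their median was 0.73 (adjusted p = 0.00322, adjusted p = 0.181 with an estimated correlation). Tnfrsf19 rose by 3.34 ± 0.18 and the Wnt inhibitor gene Apcdd1 by 3.51 ± 0.22, while Lgr5, a stem cell receptor for R-spondins, fell by 3.43 ± 0.22. Neural stem, glial and neural crest genes rose in 8 of 18 cases, fell in 1 and were not called in 9 (9 and 3 adjusted over the list alone). Their median was 0.37 (adjusted p = 0.00859, adjusted p = 0.0924 with an estimated correlation), and the list's adjusted p was 0.0602 without SGCF day 0 replicate 1. Gap43 rose by 3.80 ± 0.15 and Nefm by 3.77 ± 0.17, while neuronal genes as a list had 6 of 18 up, 4 down and an adjusted p of 0.0845. Interferon-stimulated genes fell in 10 of 16 cases, rose in 1 and were not called in 5 (12 and 1 adjusted over the list alone). Their median was -0.77 (adjusted p = 0.000862, adjusted p = 0.112 with an estimated correlation). Gbp2 changed by -1.29 ± 0.25, and macrophage markers fell in the same arrays by a median of -2.61. With all 4 day 0 arrays as 1 group, that adjusted p was 0.151. Cartilage and bone markers fell in 6 of 11 cases, rose in 1 and were not called in 4, the same adjusted over the list alone. Their median was -0.49 (adjusted p = 0.0028, adjusted p = 0.0794 with an estimated correlation). The genes called numbered 2727, with 1370 higher and 1357 lower, of which 398 and 384 changed at least 2-fold, and the count was 1488 when only the groups compared were fitted.

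At day 10 of SGCF, genes of cell division were lower throughout the list fixed for them. The mitotic checkpoint kinase gene Bub1 changed by -2.69 ± 0.21, the chromosome passenger gene Birc5 by -2.52 ± 0.18 and the replication helicase gene Mcm5 by -2.28 ± 0.15. The cell cycle inhibitor genes Cdkn1c and Cdkn2a rose by 2.69 ± 0.11 and 2.67 ± 0.13. The thyroid hormone activating enzyme gene Dio2 rose by 5.52 ± 0.17, Car3 by 5.36 ± 0.17, the glucocorticoid activating enzyme gene Hsd11b1 by 4.30 ± 0.16 and Alb by 3.58 ± 0.23. Phgdh, the entry enzyme of serine synthesis, fell by 2.77 ± 0.13.

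Of the cell cycle genes, 28 of 28 fell by day 10 of SGCF, the same adjusted over the list alone. Their median was -1.90 (adjusted p = 1.13e-20, adjusted p = 0.103 with an estimated correlation). Macrophage markers fell in 17 of 18 cases and rose in 1 (median -2.69, adjusted p = 7.8e-16). Integrated stress and unfolded protein response genes fell in 14 of 22 cases, rose in 3 and were not called in 5 (median -0.75, adjusted p = 4.44e-05). Growth arrest and secretory senescence genes rose in 11 of 16 cases, fell in 1 and were not called in 4 (median 0.93, adjusted p = 4.44e-05). Adjusted over the list alone, the counts down and up were 17 and 1, 14 and 3, and 2 and 11 in the same order. The calls of these 3 lists held with an estimated correlation, each at an adjusted p of 0.0405. Lyz2 fell by 4.41 ± 0.26, C1qa by 4.43 ± 0.14 and Asns by 2.38 ± 0.15.

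TGF-beta and myofibroblast genes were lower in 17 of 21 cases at day 10 of SGCF, higher in 2 and not called in 2 (18 and 2 adjusted over the list alone). Their median was -1.30 (adjusted p = 1.46e-08, adjusted p = 0.208 with an estimated correlation). Ccn2 changed by -3.35 ± 0.13. Cholesterol synthesis genes were lower in 12 of 17 cases and higher in 0, with 5 not called (13 and 0 adjusted over the list alone). Their median was -0.44 (adjusted p = 7.83e-05, adjusted p = 0.229 with an estimated correlation). Wnt/beta-catenin targets were higher in 11 of 17 cases, lower in 3 and not called in 3, the same adjusted over the list alone. Their median was 0.96 (adjusted p = 0.00532, adjusted p = 0.229 with an estimated correlation). Tnfrsf19 changed by 4.04 ± 0.18 and Axin2 by 3.09 ± 0.13. Targets of cAMP/CREB were higher in 10 of 18 cases, lower in 2 and not called in 6 (10 and 3 adjusted over the list alone). Their median was 0.48 (adjusted p = 0.0188, adjusted p = 0.233 with an estimated correlation). The small GTPase gene Gem changed by 2.75 ± 0.21 and the mitochondrial biogenesis coactivator gene Ppargc1a by 2.61 ± 0.24. Fibroblast identity genes were higher in 12 of 25 cases, lower in 4 and not called in 9 (14 and 4 adjusted over the list alone). Their median was 0.48 (adjusted p = 0.0353, adjusted p = 0.517 with an estimated correlation). Lum changed by 3.58 ± 0.15. Without SGCF day 0 replicate 2 the adjusted p of cAMP/CREB targets was 0.0624 and that of fibroblast identity genes 0.146, and with all 4 day 0 arrays as 1 group they were 0.0979 and 0.0754. The adipocyte genes Fabp4, a fatty acid carrier, and Adipoq, the hormone adiponectin, rose by 2.42 ± 0.17 and 2.03 ± 0.18, while the adipocyte list had 7 of 14 up, 2 down and an adjusted p of 0.215. In all, 4144 genes were called, 2192 higher and 1952 lower, of which 597 and 510 changed at least 2-fold. When only the groups compared were fitted, the count was 2712.

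**Figure D2:**
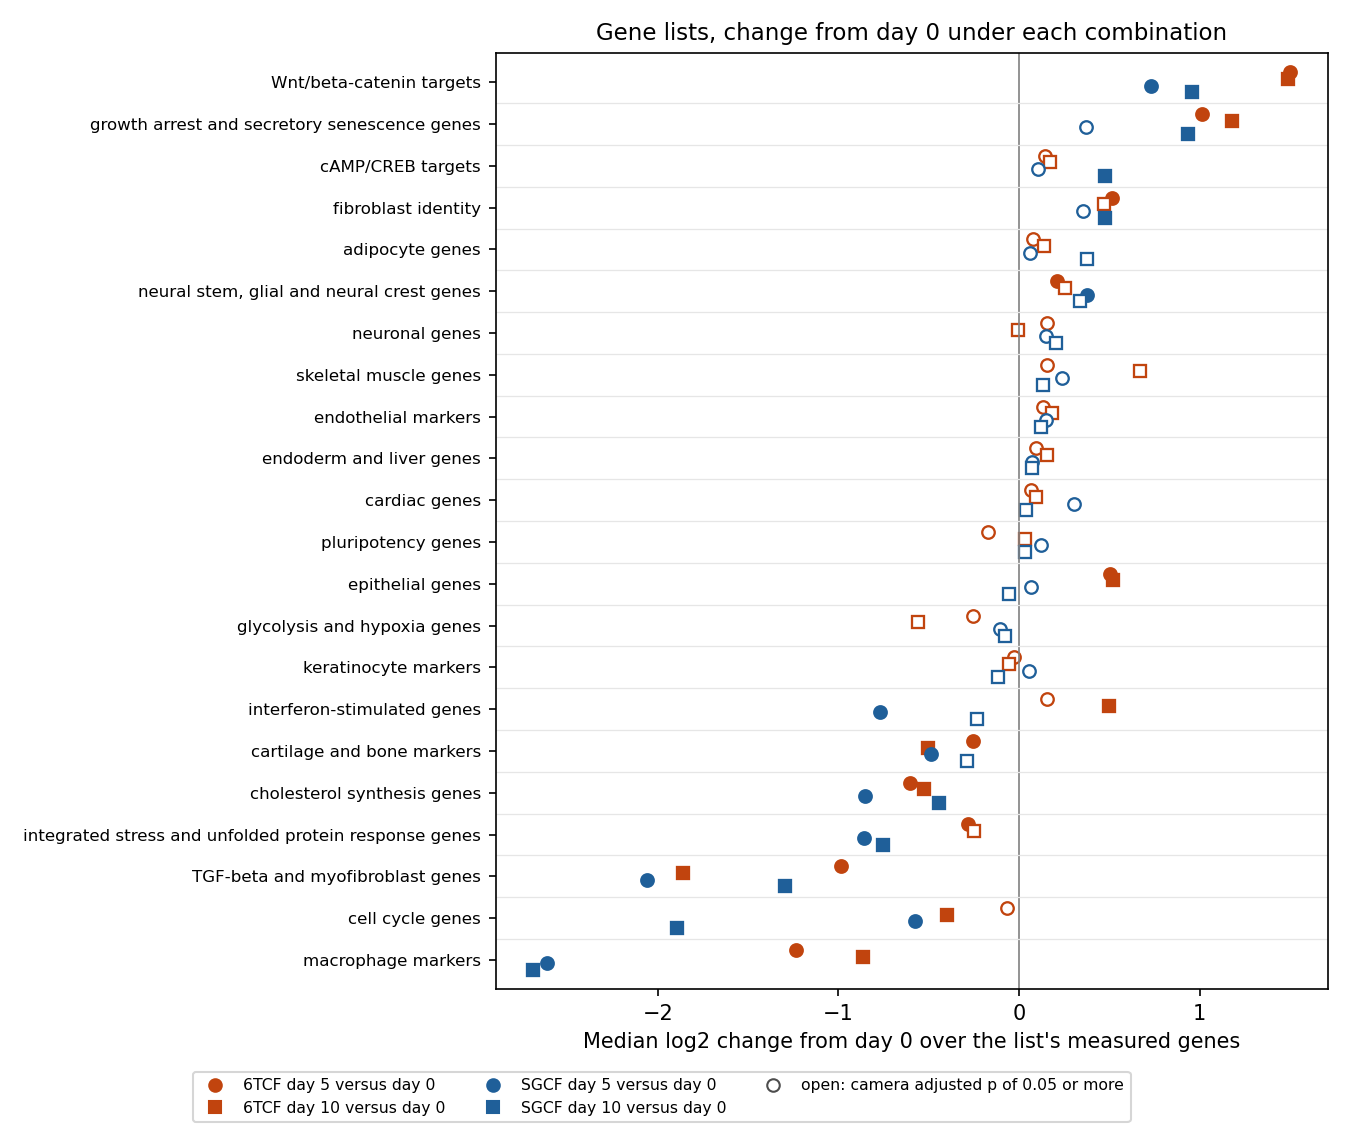
Median log2 change from day 0 over the measured genes of 22 gene lists, with circles for day 5 and squares for day 10, orange for 6TCF and blue for SGCF, filled where the camera adjusted p was under 0.05. Macrophage markers lay at -1.24 and -0.87 under 6TCF and at -2.61 and -2.69 under SGCF, and cell cycle genes at -1.90 at day 10 of SGCF.

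From day 5 to day 10 of SGCF, the proteoglycan gene Ogn rose by 3.85 ± 0.23, the growth factor gene Igf1 by 3.52 ± 0.15, the complement protease gene C1s1 by 3.76 ± 0.16 and Hsd11b1 by 3.74 ± 0.16. Nptx1 fell by 3.93 ± 0.32, Nefl by 3.39 ± 0.39 and Sox2 by 1.70 ± 0.22. Postn rose by 2.45 ± 0.13 and Lox by 2.29 ± 0.18 after their fall to day 5.

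Cell cycle genes fell in 27 of 28 cases in this step of SGCF and rose in 0 (28 and 0 adjusted over the list alone). Their median was -1.14 (adjusted p = 4.62e-22, adjusted p = 0.245 with an estimated correlation). Birc5 changed by -1.90 ± 0.18. TGF-beta and myofibroblast genes rose in 10 of 21 cases and fell in 0 (11 and 0 adjusted over the list alone). Their median was 0.37 (adjusted p = 8.06e-05, adjusted p = 0.299 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 17 cases and fell in 0, the same adjusted over the list alone. Their median was 0.30 (adjusted p = 0.00288, adjusted p = 0.299 with an estimated correlation). Cyp51 changed by 0.96 ± 0.14. Fibroblast identity genes rose in 11 of 25 cases and fell in 3 (12 and 3 adjusted over the list alone). Their median was 0.37 (adjusted p = 0.00497, adjusted p = 0.322 with an estimated correlation). The growth factor receptor gene Pdgfra changed by 1.45 ± 0.20. Adipocyte genes rose in 7 of 14 cases and fell in 0, the same adjusted over the list alone. Their median was 0.38 (adjusted p = 0.0111, adjusted p = 0.245 with an estimated correlation). Adipoq changed by 1.90 ± 0.18 and the lipoprotein lipase gene Lpl by 1.66 ± 0.16. Growth arrest and secretory senescence genes rose in 7 of 16 cases and fell in 3 (7 and 4 adjusted over the list alone). Their median was 0.29 (adjusted p = 0.0137, adjusted p = 0.258 with an estimated correlation). The collagenase gene Mmp13 changed by 3.19 ± 0.14 and Cdkn1c by 2.62 ± 0.11.

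Interferon-stimulated genes rose in 4 of 16 cases from day 5 to day 10 of SGCF and fell in 2 (7 and 2 adjusted over the list alone). Their median was 0.36 (adjusted p = 0.0111, adjusted p = 0.299 with an estimated correlation). Gbp2 changed by 2.57 ± 0.25, while macrophage markers had a median of -0.08 and were not called (adjusted p = 0.269). Targets of cAMP/CREB rose in 8 of 18 cases and fell in 0 (8 and 1 adjusted over the list alone). Their median was 0.34 (adjusted p = 0.0197, adjusted p = 0.299 with an estimated correlation), and without SGCF day 5 replicate 1 the adjusted p was 0.0908. Neuronal genes fell in 5 of 18 cases and rose in 0, the same adjusted over the list alone. Their median was -0.15 (adjusted p = 0.0274, adjusted p = 0.299 with an estimated correlation). Of the 10674 genes, 2318 were called, 1254 higher and 1064 lower, of which 340 and 219 changed at least 2-fold. The count was 1463 without SGCF day 5 replicate 1 and 1370 without SGCF day 10 replicate 2.

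At day 0 the arrays of the arms already differed. In the SGCF arm the chemokine gene Ccl12 was higher by 2.73 ± 0.21, Lgr5 by 2.38 ± 0.22, the dermal matrix gene Dpt by 2.23 ± 0.18, Saa3 by 2.22 ± 0.25 and Lum by 2.21 ± 0.15. Lower in the SGCF arm, as SGCF minus 6TCF, were the neuronal membrane glycoprotein gene Gpm6a (-2.88 ± 0.18), the uroplakin gene Upk3b (-2.19 ± 0.20), the retinal dehydrogenase gene Aldh1a1 (-2.08 ± 0.14) and the steroid synthesis gene Cyp11a1 (-2.04 ± 0.14). The comparison gives the starting point that each arm's later changes are measured from. Array brightness coincided with the arm here, so a processing batch and the arm cannot be told apart.

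Macrophage markers were higher in the SGCF day 0 arrays in 17 of 18 cases and lower in 0, the same adjusted over the list alone. Their median was 1.05 (adjusted p = 2.16e-15, adjusted p = 0.0579 with an estimated correlation). C1qa differed by 1.86 ± 0.14 and the immune receptor adaptor gene Tyrobp by 1.62 ± 0.18. Interferon-stimulated genes went with them, with 9 of 16 higher and 0 lower (10 and 0 adjusted over the list alone). Their median was 0.72 (adjusted p = 1.72e-05, adjusted p = 0.0916 with an estimated correlation), and the chemokine gene Cxcl10 differed by 1.45 ± 0.23 and Psmb8 by 1.07 ± 0.13. Cell cycle genes were higher in 8 of 28 cases and lower in 1 (14 and 1 adjusted over the list alone). Their median was 0.40 (adjusted p = 5.64e-05, adjusted p = 0.463 with an estimated correlation). Integrated stress and unfolded protein response genes were higher in 6 of 22 cases and lower in 0 (7 and 1 adjusted over the list alone). Their median was 0.25 (adjusted p = 0.00376, adjusted p = 0.0986 with an estimated correlation). Epithelial genes were lower in 8 of 19 cases and higher in 1 (10 and 1 adjusted over the list alone). Their median was -0.57 (adjusted p = 0.000783, adjusted p = 0.0674 with an estimated correlation). The desmosome gene Dsp differed by -1.46 ± 0.17 and Krt7 by -1.32 ± 0.15, and 7 of 14 mesothelium genes, whose list was written after other day 0 values had been seen, were lower and 0 higher (median -0.62). Targets of cAMP/CREB were lower in 5 of 18 cases and higher in 0, the same adjusted over the list alone. Their median was -0.25 (adjusted p = 0.00946, adjusted p = 0.27 with an estimated correlation).

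Cholesterol synthesis genes were lower in 5 of 17 cases at day 0 in the SGCF arm and higher in 0 (7 and 0 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.00946, adjusted p = 0.463 with an estimated correlation). The regulator gene Srebf2 differed by -1.03 ± 0.16, and the list's adjusted p was 0.0795 without 6TCF day 0 replicate 1. TGF-beta and myofibroblast genes were lower in 4 of 21 cases and higher in 1 (8 and 1 adjusted over the list alone). Their median was -0.25 (adjusted p = 0.0261, adjusted p = 0.593 with an estimated correlation), and their adjusted p was 0.265 without SGCF day 0 replicate 2, 0.15 with median scaling and 0.11 with cyclic loess. The genes called numbered 1857, with 917 higher and 940 lower, of which 84 and 123 changed at least 2-fold. With no scaling between arrays 7028 were called, 65 higher and 6963 lower, and 631 were called when only the groups compared were fitted. Without 6TCF day 0 replicate 1 the count was 530, without 6TCF day 0 replicate 2 it was 378, without SGCF day 0 replicate 1 it was 2987 and without SGCF day 0 replicate 2 it was 935. With no scaling between arrays, epithelial genes (adjusted p = 0.0978) and integrated stress and unfolded protein response genes (0.141) were not called.

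The change from day 0 to day 5 differed between the combinations for Lgr5, which rose under 6TCF and fell under SGCF, a difference of -5.60 ± 0.31 as SGCF minus 6TCF. The growth factor binding protein gene Igfbp5 differed by -4.81 ± 0.30, the transglutaminase gene Tgm2 by -4.09 ± 0.23 and the signalling gene Wnt4 by -3.66 ± 0.25. The uridine phosphorylase gene Upp1 (2.79 ± 0.25), the neurotrophin gene Bdnf (2.23 ± 0.29) and the immediate early gene Egr1 (2.16 ± 0.32) changed upward relative to 6TCF under SGCF. This comparison tests whether the arms changed by different amounts, and it includes their difference at day 0.

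Macrophage markers differed in 13 of 18 cases by day 5, all downward as SGCF minus 6TCF (15 adjusted over the list alone). Their median was -1.08 (adjusted p = 2.58e-13, adjusted p = 0.057 with an estimated correlation). Set side by side at day 5, the same markers had a median of -0.05 and were not called (adjusted p = 0.708). The macrophage growth factor receptor gene Csf1r differed by -2.95 ± 0.19. Interferon-stimulated genes differed downward in 8 of 16 cases and upward in 0 (9 and 1 adjusted over the list alone). Their median was -0.69 (adjusted p = 7.16e-05, adjusted p = 0.143 with an estimated correlation). Gbp2 differed by -2.63 ± 0.35, but side by side at day 5 the list was not called (median -0.12, adjusted p = 0.844). Integrated stress and unfolded protein response genes differed downward in 5 of 22 cases and upward in 0 (10 and 1 adjusted over the list alone). Their median was -0.40 (adjusted p = 5.37e-05, adjusted p = 0.057 with an estimated correlation), and side by side they were not called either (median -0.12, adjusted p = 0.174). Cell cycle genes differed downward in 4 of 28 cases and upward in 0 (6 and 0 adjusted over the list alone). Their median was -0.51 (adjusted p = 4.92e-05, adjusted p = 0.396 with an estimated correlation, adjusted p = 0.052 with fry), and set side by side at day 5 they were not called (median -0.06, adjusted p = 0.504).

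Fibroblast identity genes differed downward in 11 of 25 cases by day 5 and upward in 1 (12 and 1 adjusted over the list alone). Their median was -0.58 (adjusted p = 5.12e-05, adjusted p = 0.272 with an estimated correlation). Lum differed by -2.42 ± 0.21, but set side by side at day 5 it stood at -0.21 ± 0.15 and was not called, and Pdgfra differed by -1.77 ± 0.28. TGF-beta and myofibroblast genes differed downward in 9 of 21 cases and upward in 1 (10 and 1 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.000287, adjusted p = 0.373 with an estimated correlation). Postn differed by -2.83 ± 0.18. Wnt/beta-catenin targets differed downward in 7 of 17 cases and upward in 0 (9 and 1 adjusted over the list alone). Their median was -0.60 (adjusted p = 0.000548, adjusted p = 0.186 with an estimated correlation). Notum differed by -1.19 ± 0.20. Cholesterol synthesis genes differed downward in 5 of 17 cases and upward in 0 (6 and 0 adjusted over the list alone). Their median was -0.45 (adjusted p = 0.000299, adjusted p = 0.272 with an estimated correlation). Cyp51 differed by -1.14 ± 0.20. Epithelial genes differed downward in 6 of 19 cases and upward in 3 (7 and 3 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.0207, adjusted p = 0.158 with an estimated correlation). Krt18 differed by -1.57 ± 0.25, and the list's adjusted p was 0.136 without SGCF day 0 replicate 2. The difference was called for 958 genes, 311 upward and 647 downward as SGCF minus 6TCF, of which 137 and 407 differed at least 2-fold. The actin 3' minus 5' signal had moved by 0.48 under 6TCF and 0.12 under SGCF. That of Gapdh went from 0.39 to 0.50 and from -0.02 to 0.10. Side by side at day 5, the fibroblast identity, TGF-beta and myofibroblast, Wnt/beta-catenin, cholesterol synthesis and epithelial lists were called at the preset correlation (adjusted p of 1.88e-08 to 0.00168) and 0 lists with an estimated correlation. Of these, the TGF-beta and myofibroblast, cholesterol synthesis and epithelial lists were already called lower in the SGCF arm at day 0 at the preset correlation. The difference was called for 598 genes without 6TCF day 0 replicate 1 and for 566 without 6TCF day 0 replicate 2, and 2520 genes were called when the arms were set side by side at day 5.

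By day 10 the difference in change was called for 7 lists at the preset correlation, 5 downward, among them cell cycle genes, epithelial genes and macrophage markers, and 2 upward, and for 0 lists with an estimated correlation. Birc5 differed by -2.26 ± 0.25 as SGCF minus 6TCF, Krt19 by -2.77 ± 0.20, Krt18 by -2.46 ± 0.25, Lyz2 by -3.50 ± 0.37 and Ccl8 by -3.60 ± 0.32. Lgr5 still differed by -4.75 ± 0.31. In the other direction Col11a1 differed by 2.73 ± 0.33, the forkhead transcription factor gene Foxc1 by 2.47 ± 0.21, Egr1 by 2.42 ± 0.32 and Bdnf by 2.27 ± 0.29.

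Cell cycle genes differed downward in 24 of 28 cases by day 10 and upward in 0 (26 and 0 adjusted over the list alone). Their median was -1.44 (adjusted p = 1.33e-15, adjusted p = 0.143 with an estimated correlation), and set side by side at day 10 they had a median of -1.02 with 24 of 28 lower (adjusted p = 6.3e-15, adjusted p = 0.201 with an estimated correlation). Macrophage markers differed downward in 17 of 18 cases and upward in 0 (18 and 0 adjusted over the list alone). Their median was -1.56 (adjusted p = 1.29e-14, adjusted p = 0.0694 with an estimated correlation), and side by side 10 of 18 were lower (median -0.76, adjusted p = 4.56e-05, adjusted p = 0.201 with an estimated correlation). Interferon-stimulated genes differed downward in 9 of 16 cases and upward in 0 (11 and 0 adjusted over the list alone). Their median was -0.78 (adjusted p = 0.000199, adjusted p = 0.12 with an estimated correlation), and side by side they were not called (median -0.09, adjusted p = 0.316). Bst2, which tethers enveloped virions, differed by -2.24 ± 0.21. Integrated stress and unfolded protein response genes differed downward in 8 of 22 cases and upward in 1 (10 and 2 adjusted over the list alone). Their median was -0.44 (adjusted p = 0.00151, adjusted p = 0.116 with an estimated correlation), and side by side they were not called (median -0.11, adjusted p = 0.0869). Of the serine synthesis genes, Phgdh differed by -2.05 ± 0.18 and Psat1 by -1.77 ± 0.17.

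Epithelial genes differed downward in 8 of 19 cases by day 10 and upward in 1 (9 and 3 adjusted over the list alone). Their median was -0.48 (adjusted p = 0.00689, adjusted p = 0.116 with an estimated correlation). Side by side at day 10, 12 of 19 were lower under SGCF (median -0.86, adjusted p = 1.11e-07), a call that held with an estimated correlation (adjusted p = 0.0174). The list was already lower in the SGCF arm at day 0. The side by side comparison holds that gap and any processing batch that goes with the arm, so it is not a measure of the response alone. The 14 mesothelium genes had a median change of 1.23 under 6TCF and 0.27 under SGCF by day 10, a difference not tested as a list here, and Krt18 and Krt19 belong to the mesothelium list as well. Of the TGF-beta and myofibroblast genes, the difference was upward in 8 of 21 cases and downward in 1 (11 and 1 adjusted over the list alone). Their median was 0.48 (adjusted p = 0.0022, adjusted p = 0.547 with an estimated correlation). Side by side at day 10 their median was 0.21 (adjusted p = 0.0257, adjusted p = 0.653 with an estimated correlation). The matrix gene Tnc differed by 2.08 ± 0.31 and Col8a1 by 1.68 ± 0.23. Targets of cAMP/CREB differed upward in 4 of 18 cases and downward in 0, the same adjusted over the list alone. Their median was 0.42 (adjusted p = 0.00437, adjusted p = 0.177 with an estimated correlation), and side by side they were not called (median 0.15, adjusted p = 0.272). The nuclear receptor gene Nr4a2 differed by 1.81 ± 0.20. Lum differed by -1.65 ± 0.21, but side by side at day 10 it was higher under SGCF by 0.57 ± 0.15. By day 10 the actin 3' minus 5' signal had moved by 0.69 under 6TCF and 0.13 under SGCF and that of Gapdh by 0.10 and 0.13. The difference was called for 2740 genes, 1309 upward and 1431 downward as SGCF minus 6TCF, of which 439 and 600 differed at least 2-fold. The count was 1672 without 6TCF day 0 replicate 1, 1447 without 6TCF day 0 replicate 2 and 1463 without 6TCF day 10 replicate 1.

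**Figure D3:**
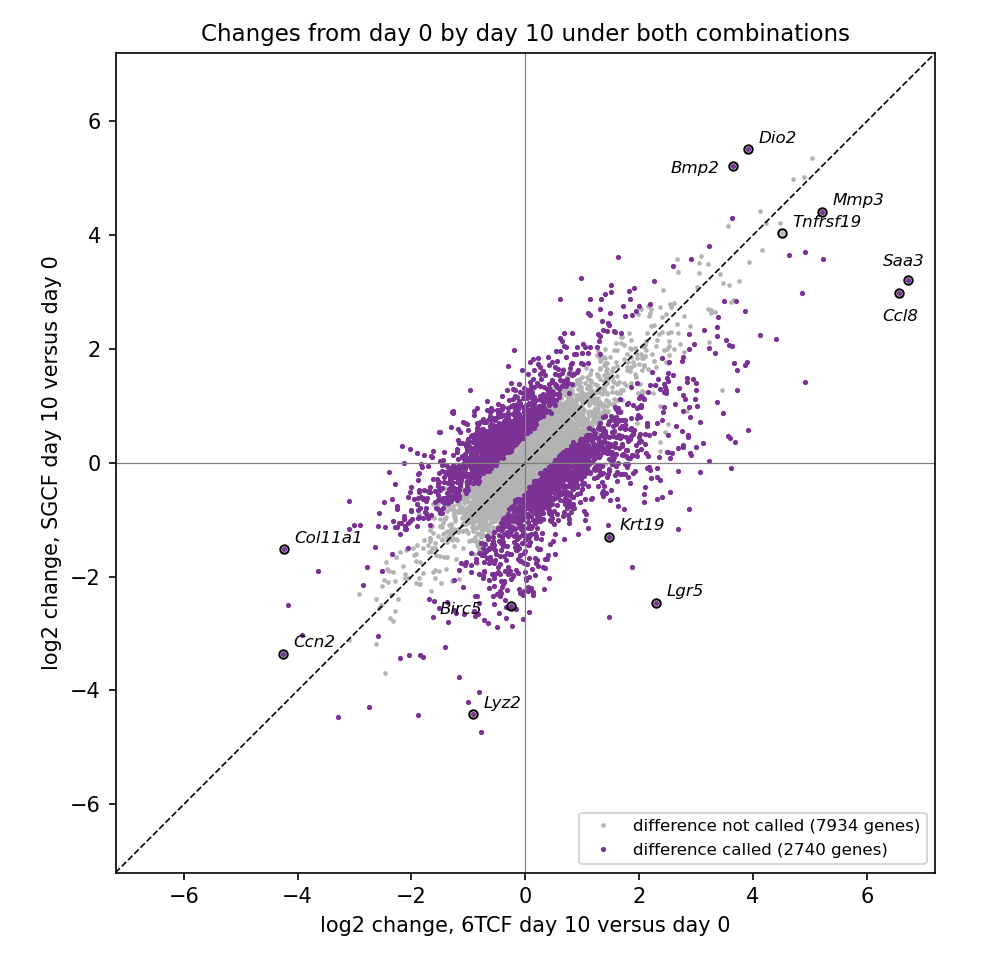
Log2 change from day 0 to day 10 under 6TCF (horizontal) and under SGCF (vertical) for 10674 genes, with the 2740 genes whose difference was called in purple, the others in grey and a dashed line where both changes are equal. Mmp3 lies at 5.21 under 6TCF and 4.42 under SGCF, and Lgr5 lies at 2.29 under 6TCF and -2.46 under SGCF.

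Much of the change from day 0 was shared by the arms. With no array labelled as an untreated culture at day 5 or 10, shared effects of the chemicals cannot be told apart from time in culture and medium. Of the genes called from day 0 to day 10 in both arms, 1224 rose in both, where 508.9 would be shared if the calls were independent, 975 fell in both, where 391 would be, and 228 went in opposite directions, where 892.2 would. At day 5 the counts were 778, 638 and 105, where 207.5, 170.5 and 377.7 would be expected. Tnfrsf19, Bmp2, Mmp3 and Lum rose in both arms at both days, and Ccn2 and C1qa fell. Across genes, the changes of the arms correlated at r = 0.645 and rho = 0.525 by day 5 and at r = 0.609 and rho = 0.479 by day 10, where genes are not independent replicates. Of the 6333 genes called in either arm by day 10, the difference was called for 2627, and of 4164 by day 5 for 945.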

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

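The test of whether array brightness overlaps between the arms, the comparison of macrophage markers with other fallen genes and with random lists, and the test of the cell cycle genes within each arm were chosen only after the results were seen.

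At day 0, 1857 genes differed between the arms, a count of 530 without 6TCF day 0 replicate 1, 378 without 6TCF day 0 replicate 2, 2987 without SGCF day 0 replicate 1 and 935 without SGCF day 0 replicate 2. Against the choice of scaling for array brightness as the whole explanation, 87.1% of the called genes stayed called in the same direction under median scaling and 93.2% under cyclic loess. Each scaling used the same arrays, so effects of brightness that scaling leaves in place were not tested. What stays open is a processing batch, which cannot be told apart from the arm, because the lowest array median of the 6TCF arm was 1.19 times the highest of the SGCF arm and no array of either arm lay in the range of the other. A difference between the starting cells of the 2 arms is also open, with macrophage markers higher in the SGCF arm in 17 of 18 cases (median 1.05, not called with an estimated correlation) and mesothelium genes lower in 7 of 14 (median -0.62), values that the same batch could enter. The differences between the combinations by days 5 and 10 subtract these day 0 values. An offset that is constant over all arrays of an arm would cancel there, but would stay in the side by side comparisons. Whatever set the day 0 arrays apart without lasting equally to the later days may enter the differences.

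Macrophage markers fell from day 0 in each arm. Their median difference in change, SGCF minus 6TCF, was -1.08 by day 5 and -1.56 by day 10. With an estimated correlation, neither difference nor the fall under 6TCF was called. Side by side at day 5 the arms had a median of -0.05 and were not called, after a day 0 gap of 1.05. Some markers lay by then close to the filter level of log2 5.25, where a further fall is compressed. At day 5 C1qa stood at 5.01 under 6TCF and 5.34 under SGCF, and C1qb at 5.15 and 5.05. Others stayed above that level, such as Lyz2 at 8.08 and 7.63 and Csf1r at 8.30 and 6.58. As a list the markers thus stood level between the arms at day 5, so the difference in change by then mirrors the higher SGCF start. By day 10 they were also lower under SGCF side by side at the preset correlation, so the start makes up only part of that difference. How far the low signal enters either difference was not tested. Scaling between arrays is argued against, since the highest median change at day 10 over the 2 arms and 2 other scalings was -0.904, with -2.69 the lowest. A smaller share of macrophages in the cultures stays open as a hypothesis: over the 12 arrays the 18 markers had a median pairwise r of 0.915 (highest of 1000 random lists 0.294), but 283 other genes that fell in each arm had 0.78, so moving together does not separate fewer macrophages from lower expression in the cells present. Within groups, with the group means removed, the r was 0.179, and under 6TCF Cd14 went from 6.64 at day 0 to 7.96 at day 10 and Csf1r from 8.13 to 8.09, both named after their values were seen. Among the abundant markers, Lyz2 went from 10.53 to 9.62 under 6TCF and from 11.68 to 7.27 under SGCF, 0 of the 18 markers stand in another list used here, and no sort that would remove such cells is given in the sources used here.

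The change by day 10 differed between the combinations at 2740 genes (1672 without 6TCF day 0 replicate 1, 1447 without 6TCF day 0 replicate 2 and 1463 without 6TCF day 10 replicate 1), while the 3' minus 5' signal moved by 0.69 under 6TCF and 0.13 under SGCF for actin and by 0.10 and 0.13 for Gapdh. For the 28 cell cycle genes (median difference -1.44), the highest median change over 3 scalings was -0.379 under 6TCF (SD over genes 0.37, quantile) and -1.81 under SGCF. Signal lost from these genes in the 6TCF day 10 arrays would move the difference upward, and it was downward. For the cell cycle genes as a set, these values argue against such loss as the source of the difference. A signal raised there by the scaling, from a fall shared by both arms, is argued against too. The 6TCF array medians were 131.3 and 140.6 at day 0 and 126.3 and 142 at day 10. With no scaling, the median of all genes in this step shifted by -0.0374. Under median scaling the cell cycle median under 6TCF was -0.436. For the other genes, loss of 5' ends or of long transcripts in those arrays stays open. It cannot be told apart there from different effects of the combinations. The share called among the genes with the shortest spans was 80.6% of that among the longest (SE 3.21, 3 groups of equal size). That met the bound of at least 80% fixed against this explanation, but by less than its SE, a margin the bound as written did not include. The SE is binomial over genes, which are not independent replicates. Of the calls, 31.4% were higher among the shortest and 65.5% among the longest. Gene span is genomic and not transcript length. Neither these shares nor the cell cycle median of -1.43 after a lowess on span therefore decides whether transcripts were lost. Different effects of the 2 combinations were not tested apart from that, and the day 0 difference above enters here as well.

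A test of the difference in change between the combinations singled out 958 genes by day 5 (598 without 6TCF day 0 replicate 1 and 566 without 6TCF day 0 replicate 2), and among the largest, as SGCF minus 6TCF, were Lce1h (3.04), Upp1 (2.79), Bdnf (2.23), Esm1 (2.19), Egr1 (2.16), Nptx1 (2.13, and 1.82 and no longer called without 6TCF day 5 replicate 2), Elavl4 (2.08) and Mcpt8 (2.07). In the other direction were Lgr5 (-5.60), Igfbp5 (-4.81), Tgm2 (-4.09), Egfl6 (-3.71), Wnt4 (-3.66), Adamts15 (-3.62), Lpl (-3.51) and Saa3 (-3.45). These values include the day 0 gap, which varied by gene. Saa3 stood at 5.94 in the 6TCF arm and 8.15 in the SGCF arm at day 0, and at 9.70 and 8.47 at day 5. Wnt4 stood at 7.06 and 7.42 at day 0, and at 10.37 and 7.07 at day 5. The same test applied to gene lists, which called 0 of them with an estimated correlation, gave medians by day 5 of -0.58 for fibroblast identity, -0.41 for TGF-beta and myofibroblast genes, -0.60 for Wnt/beta-catenin targets, -0.41 for epithelial genes, -0.51 for cell cycle genes, -0.69 for interferon-stimulated genes, -0.45 for cholesterol synthesis genes and -0.40 for integrated stress and unfolded protein response genes. Side by side at day 5 the cell cycle, interferon-stimulated and integrated stress lists were not called (adjusted p = 0.504, 0.844 and 0.174). Over their alternatives the adjusted p of epithelial genes ran from 0.0025 to 0.158 (0.136 without SGCF day 0 replicate 2) and that of cell cycle genes from 1.39e-05 to 0.396.

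By day 10 that test gave Col11a1 (2.73), Foxc1 (2.47), Egr1 (2.42), Lcn2 (2.27), Bdnf (2.27), Kng1 (2.27), Lpin1 (2.255) and Zfhx3 (2.23), and in the other direction Lgr5 (-4.75), Pkia (-4.18), Lyz1 (-3.96), Crip1 (-3.85), Angptl7 (-3.705), Serpinb1a (-3.70), Ccl12 (-3.68) and Ccl8 (-3.60). The day 0 gap is part of these values too. Ccl12 stood at 5.41 in the 6TCF arm and 8.15 in the SGCF arm at day 0, and at 8.28 and 7.33 at day 10. Egr1 stood at 11.09 and 11.04 at day 0, and at 7.995 and 10.36 at day 10. The lists, of which 0 were called with an estimated correlation, had medians by day 10 of 0.48 for TGF-beta and myofibroblast genes, 0.42 for cAMP/CREB targets, -0.48 for epithelial genes, -0.78 for interferon-stimulated genes and -0.44 for integrated stress and unfolded protein response genes. Side by side at day 10 the cAMP/CREB, interferon-stimulated and integrated stress lists were not called (adjusted p = 0.272, 0.316 and 0.0869).

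Control probe sets that the comparisons do not use had a 3' minus 5' signal above that of both day 0 arrays of the same arm, for actin by 0.48 at day 5 and 0.69 at day 10 of 6TCF and by 0.12 and 0.13 at the same days of SGCF, and for Gapdh by 0.10 at day 10 of 6TCF and 0.12 and 0.13 at days 5 and 10 of SGCF (log2, group means).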

How the results depend on the processing

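The settings with no scaling between arrays, cyclic loess and no pseudocount, those that leave an array out of the gene list tests, and the scaling, probe set and pseudocount settings of the correlations were chosen after seeing the data. Quantile normalization, planned as an alternative for values already normalized, is the setting reported here. Of 775 calls of named genes, those lost with the direction kept numbered 14 with median scaling, 12 of 774 with cyclic loess, 15 with trend and robust variances, 30 of 769 with the mean of a gene's probe sets, 10 with no filter, 0 of 704 with a filter at the 50th percentile, 39 with no pseudocount, 52 with only the arrays of the groups compared and 25 of 375 with the day 0 arrays pooled. With no scaling, 83 of 774 were lost and 5 reversed. Without subtracting day 0, 27 of 167 were lost and 9 reversed. With 1 array left out, 540 of 3768 were lost, and with the replicate block 16.

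Every probe set on its own, which adds tests, called 4821 and 7619 at days 5 and 10 of 6TCF, 4267 and 6625 at days 5 and 10 of SGCF, 3610 between these days of SGCF and 3253 at day 0. Only the arrays of the groups compared, which leaves fewer arrays for the variance, called 1488 and 2712 genes at days 5 and 10 of SGCF and 631 at day 0. No scaling called 1208 genes between days 5 and 10 of SGCF (the cause was not tested) and 7028 at day 0, 65 higher and 6963 lower, where the median of all genes shifted by -0.64. That shift was -0.21 at day 5 of 6TCF, 0.17 between its days 5 and 10, -0.30 and -0.26 at days 5 and 10 of SGCF and -0.235 in the difference by day 10, and at most 0.1 in size in the remaining comparisons and under median scaling and cyclic loess. Relative to the day 0 shift, the genes reversed there by no scaling had moved up: Bmp4 (-0.35), Birc5 (-0.0838), Ube2c (-0.0843), Psat1 (-0.11) and Flt1 (-0.0116).

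Without subtracting day 0, the difference by day 5 was called for 2520 genes, and the comparison then holds the arms' day 0 difference. Reversed there were Fabp7 (-0.22), Myl7 (-0.35) and Col2a1 (-0.29) by day 5, and Lum (0.57), Col6a2 (0.0643), Srebf2 (-0.19), Hsd17b7 (-0.46), Flt4 (-0.0261) and Kdr (-0.0324) by day 10. The correlation between the arms' changes by day 5, 0.645 as reported with genes that are not independent replicates, was 0.67 with a filter at the 50th percentile, 0.633 with every probe set, 0.628 with no pseudocount and 0.688 over called genes, and the cause was not tested.

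Of the 76 list tests called, 5 were called with a correlation estimated per list, which widens their variance. Calls lost were 4 with fry, 3 with no filter, 2 each with median scaling, the mean of probe sets and no scaling, 1 with cyclic loess, 5 of 37 with the day 0 arrays pooled and 11 of 368 with 1 array left out. Cartilage and bone markers at day 5 of 6TCF had an adjusted p of 0.0518 with no filter and 0.057 with day 0 pooled (3.25e-06 to 0.101 over the alternatives), neural stem, glial and neural crest genes there 0.0628 with the mean of probe sets (6.55e-05 to 0.101) and neuronal genes between days 5 and 10 of SGCF 0.0968 with no filter (0.00167 to 0.299). Skeletal muscle genes between days 5 and 10 of 6TCF had 0.167 with fry, 0.0649 with median scaling, 0.0692 with no filter and 0.0528 with the mean of probe sets (3.35e-06 to 0.649), and TGF-beta and myofibroblast genes at day 0 had 0.14 with fry (0.00498 to 0.593).

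With the replicate block, the genes called numbered 2856 and 4517 at days 5 and 10 of 6TCF, 1483 between them, 2584 and 3997 at days 5 and 10 of SGCF, 2153 between them, 1627 at day 0, and 911 and 2533 in the differences by days 5 and 10, with 76 list tests called. Replicate numbers did not pair the arrays: over 15 pairs of groups their r ran from -0.277 to 0.11, with 2 over 0.1.

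With 1 array left out, where the lone array of its group is assumed to vary like the others, the count ran from 1757 to 2391 and from 3216 to 3586 at days 5 and 10 of 6TCF, from 370 to 1448 between them, from 1849 to 2886 and from 3074 to 4404 at days 5 and 10 of SGCF, from 1370 to 1634 between them, from 378 to 2987 at day 0, and from 566 to 1327 and from 1447 to 3830 in the differences by days 5 and 10. List tests called ran from 73 to 79, and the correlations from 0.615 to 0.647 by day 5 and from 0.523 to 0.664 by day 10. Low signal limits part of these results, since the filter asked for 1 group mean above log2 5.25 and the added 16 compresses changes near the background. Between 5.04% (days 5 to 10 of 6TCF) and 19.3% (the difference by day 5) of the called genes had a compared group under that level.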

Other observations

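Single genes of lists that were not called as lists changed under each combination. The transcription factor gene Gata6, which stands in the cardiac and in the endoderm and liver lists, rose by 1.73 ± 0.13 at day 10 of 6TCF and by 1.82 ± 0.13 at day 10 of SGCF. Isl1, a transcription factor gene of heart and neuron progenitors, rose by 1.79 ± 0.17 at day 5 of 6TCF and by 1.38 ± 0.17 at day 5 of SGCF, while the natriuretic peptide gene Nppb changed by -1.72 ± 0.18 and -1.25 ± 0.18. The pluripotency list's Klf4 changed by -1.61 ± 0.21 and -1.23 ± 0.21 at day 10, and the keratinocyte list's connexin gene Gjb2 by -1.63 ± 0.12 and -2.71 ± 0.12. Of the endothelial markers, Kdr rose by 1.42 ± 0.13 and Flt1 changed by -1.36 ± 0.19 at day 10 of SGCF.

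Among the glycolysis and hypoxia genes, which were not called as a list in the difference by day 10 (7 of 21 up, 4 down, adjusted p = 0.318), the 4 with the largest called differences went in both directions. By day 10 the difference in change, SGCF minus 6TCF, was 1.69 ± 0.21 for the glucose transporter gene Slc2a1 and 2.06 ± 0.29 for the hexokinase gene Hk2, and -2.00 ± 0.27 for the aldolase gene Aldoc and -2.41 ± 0.21 for Egln3, whose enzyme marks hypoxia-inducible factors for breakdown. Under 6TCF itself Aldoc rose by 2.65 ± 0.19 and Egln3 by 2.32 ± 0.15 by day 10, and Hk2 changed by -1.52 ± 0.20.

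One hypothesis was formed from the genes called at day 0: the 6TCF cultures may have held more mesothelial cells, or cells with their expression, than the SGCF cultures, and the rise of keratin genes under 6TCF might go with them. The test of the same genes under SGCF was chosen after the values were seen. The list of mesothelium genes was written after the day 0 genes had been seen, and the other tests used only the 19 members not yet looked at, of which 14 were measured. At day 0 these were lower in the SGCF arm as a set, 7 lower and 0 higher with a median of -0.62 (camera p = 3.16e-05, p = 0.00445 with an estimated correlation). By day 10 of 6TCF they had risen as a set, 11 higher and 1 lower with a median of 1.23 (camera p = 1.11e-05, p = 0.00342 with an estimated correlation). By day 10 of SGCF they also tended up as a set, 5 higher and 2 lower with a median of 0.27 (camera p = 0.0205, p = 0.0489 with an estimated correlation), among them Efemp1 (1.84 ± 0.17), Dpp4 (1.74 ± 0.14), Pdpn (1.41 ± 0.12) and Rspo1 (1.39 ± 0.17), while 0 of the list's 4 keratin genes rose and Krt19 (-1.30 ± 0.14) and Krt7 (-1.003 ± 0.15) were lower. Some of these genes thus rose there without the keratins, so a link of the keratin rise under 6TCF to mesothelial cells stays open. Among members chosen after their values were seen, Wt1 differed by -1.48 ± 0.18 at day 0 and rose by 2.88 ± 0.18 by day 10 of 6TCF, while mesothelin, Msln, changed by -2.12 ± 0.14 in the same step, which a plain rise in the number of such cells does not account for. Under 6TCF the abundant members Krt18 and Upk3b went from 8.26 to 11.02 and from 9.45 to 10.88, and Ezr from 10.20 to 10.97. The 14 tested genes were limited to those that passed the expression filter, which needs 1 group mean above its level. Passing it is therefore no result. The 4 keratin genes outside the test stand in the epithelial list as well, and no sort that would remove such cells is given in the sources used here. The day 0 part shares its arrays with a processing batch that cannot be told apart from the arm, and the test by day 10 does not separate growth of such cells from induction of these genes in fibroblasts.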
